A study of Gallus gallus with 6 samples.

How the data were processed

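Poly(A)-selected RNA from 6 wells of ICP1 cells, an immortalized line of chicken preadipocytes, was sequenced 48 h after transfection. EV libraries came from 3 wells given the empty pCMV-myc expression plasmid, and KLF2 libraries from 3 wells given the same plasmid carrying KLF2. Per the labels' protocols a well counted as a biological replicate, so p-values measure the spread between wells of a single line. Nothing in the protocols describes a step that marks strand, so reads from a stretch that a gene shares with an overlapping or antisense gene cannot be told apart.

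Per the submitters' processing notes, fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used with the build GRCg7b. The program that normalized and tested the counts is not given in the sources used here. The authors' deposited table holds 18495 genes with identifiers, names, coordinates and biotypes, of which 336 come without an Ensembl identifier. Per the file headers it also gives a log2 fold change, a p-value and an adjusted p per gene. The deposited signal per gene and library is a normalized count. Each value divided by the smallest nonzero value of its library came out whole for 100% of values (tolerance 1e-06), so the read counts behind them were recovered. Totals were 13551627, 13434600 and 14058957 reads in EV 1 to 3, and 13431679, 13255169 and 14168807 reads in KLF2 1 to 3. The size factors implied by the authors' values equalled median-of-ratios factors computed from the recovered reads. Every gene in the table had at least 2 reads in total.

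The design fixed before the data were examined called for edgeR's quasi-likelihood test with TMM normalization on raw counts. Where the file held no raw counts, it called for limma. Because the authors' values are normalized counts, limma 3.58.1 in R 4.3.3 gave the main result: robust limma-trend on log2(normalized count + 1), for the 16765 genes with a mean of at least 1 in either group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Intervals are at the 95% level. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives.

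Gene lists were 31 sets of symbols written before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Of 1128 distinct symbols, 853 were among the tested genes and 250 were not found by name. Exact symbols were used for matching. That choice was made after both matchings had been run: adding 28 matches through synonyms in a RefSeq name table took the called lists from 6 to 7.

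The rule for named genes, fixed beforehand, took KLF2 and GATA2, 6 adipogenic genes (PPARG, CEBPA, FABP4, LPL, PLIN1, ADIPOQ), the 12 largest increases and 12 largest decreases past the threshold with a symbol, a mean of at least 1 CPM and no overlap between groups, and up to 4 members per list past the threshold. No gene passed, so the last 2 parts named none. The other genes in the text were chosen after their values were seen: the 12 per direction with the lowest unadjusted p under the same level and separation criteria, the up to 4 lowest-p members of a list, the 10 lowest-p genes at any level, the 4 protein-coding genes with the largest loadings on the first principal component, and 4 epithelial genes.

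The method was tested on counts simulated from the real means, size factors and edgeR's trended dispersions, in 5 runs of about 16316 tested genes with 200 changed genes each. It recovered 9.54% of genes changed 1.5-fold, 39.7% of those changed 2-fold, 64.7% of those changed 4-fold and 78.1% of those changed 8-fold. No gene was called with the wrong sign, and 29 unchanged genes were called over the 5 runs. A list of 40 genes shifted 1.5-fold was called in 5 of 5 runs. The simulation held independent noise, without any component shared between genes.

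Alternatives covered normalization, test, filter, pseudocount, gene set, replicate block and leaving out each library. EV 1 and KLF2 3 were the 2 libraries with the most ribosomal RNA reads. Added after seeing that 0 genes had passed were leaving out EV 1 and KLF2 3 together, matching by synonyms, and edgeR with TMM on the recovered reads. The last was the design's test for raw counts. Also added then were 4 corrections for differences between libraries: removal of the gene length trend by loess with a span of 0.5, a microchromosome score as a covariate, array weights, and the first residual component as a covariate. The score is the median deviation of genes on chromosomes 11 to 28 and 30 to 38 minus that of genes on chromosomes 1 to 5 and Z, over genes with a mean of at least 20. The residual component was taken from the spread within groups of these same data, so its p-values are too low by construction.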

Results

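The series asked what transfection of KLF2, a zinc-finger transcription factor of the Krüppel-like family, did to the transcriptome of chicken preadipocytes, with particular interest in GATA2, a transcription factor known to restrain adipogenesis, and in adipogenic genes. Expression was measured in 3 EV and 3 KLF2 libraries taken at 48 h. Depth was even, from 13255169 to 14168807 assigned reads per library, and 15469 to 16090 genes were detected in each.

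KLF2 itself had a mean normalized count of 1694 ± 683 (SD, n = 3) in KLF2 libraries and 822 ± 236 (SD, n = 3) in EV libraries, 2.06 times higher. The gene, ENSGALG00010027941, lies on chromosome 28 from 4830903 to 4833376 in GRCg7b. Its values were 1093, 675 and 697 in EV 1 to 3 and 1052, 1618 and 2412 in KLF2 1 to 3, so the EV 1 value lay above the KLF2 1 value. The log2 fold change was 1.00 (SE 0.31, 95% interval 0.28 to 1.72). It did not pass the threshold in limma with Benjamini-Hochberg adjustment (adjusted p = 0.962), and an exact two-sided permutation test gave p = 0.2. Among the 8545 genes with a mean of at least 10 CPM, KLF2 had the highest log2 fold change, a ranking made after its value was seen. Reads from the plasmid and from the chromosomal gene were counted together. With EV 1 and KLF2 3 left out, a setting chosen after seeing the data, the log2 fold change was 0.93. KLF2 then passed in limma (adjusted p = 0.0184, range over the alternatives 2.83e-08 to 1.00). EV 1 was the only EV library above a KLF2 library, so leaving it out ended the overlap by construction. This pass is therefore not read as support. The 2.83e-08 came from limma with the first residual component as a covariate, which lowers p by construction, and is not read as support.

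GATA2 had a mean of 465 ± 88.3 (SD, n = 3) in KLF2 libraries and 529 ± 129 (SD, n = 3) in EV libraries. This gene, ENSGALG00010026920, lies on chromosome 12 from 9385018 to 9395368. Its log2 fold change was -0.17 (SE 0.21, 95% interval -0.63 to 0.29), and an exact two-sided permutation test gave p = 0.5, where the smallest p that 3 against 3 allows is 0.1. The groups overlapped, and a higher GATA2 level in KLF2 libraries was not detected. Without EV 2 the log2 fold change was -0.37 and without EV 1 it was -0.00472; with the microchromosome score as a covariate, a correction added after seeing the data, it was 0.0074.

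None of the 6 adipogenic genes passed the threshold. PPARG, the nuclear receptor that drives adipocyte differentiation, had means of 202 ± 40.6 (SD, n = 3) in KLF2 and 197 ± 37.8 (SD, n = 3) in EV libraries, a log2 fold change of 0.04 whose sign turned when EV 1, KLF2 1 or KLF2 2 was left out. CEBPA, its partner factor, had means of 54.9 and 73.6 (log2 fold change -0.42, SE 0.33). FABP4, a fatty acid carrier, had means of 23.9 and 31.2 (log2 fold change -0.38, SE 0.36). LPL and PLIN1 were near the floor, with means of 7.69 and 1.64 in KLF2 libraries and 9.21 and 3.35 in EV libraries. ADIPOQ, which encodes adiponectin, had a mean of 1.00 in KLF2 and 4.97 in EV libraries without overlap (log2 fold change -1.53, SE 0.63), at counts too low to read a fold change with confidence.

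**Figure D1:**
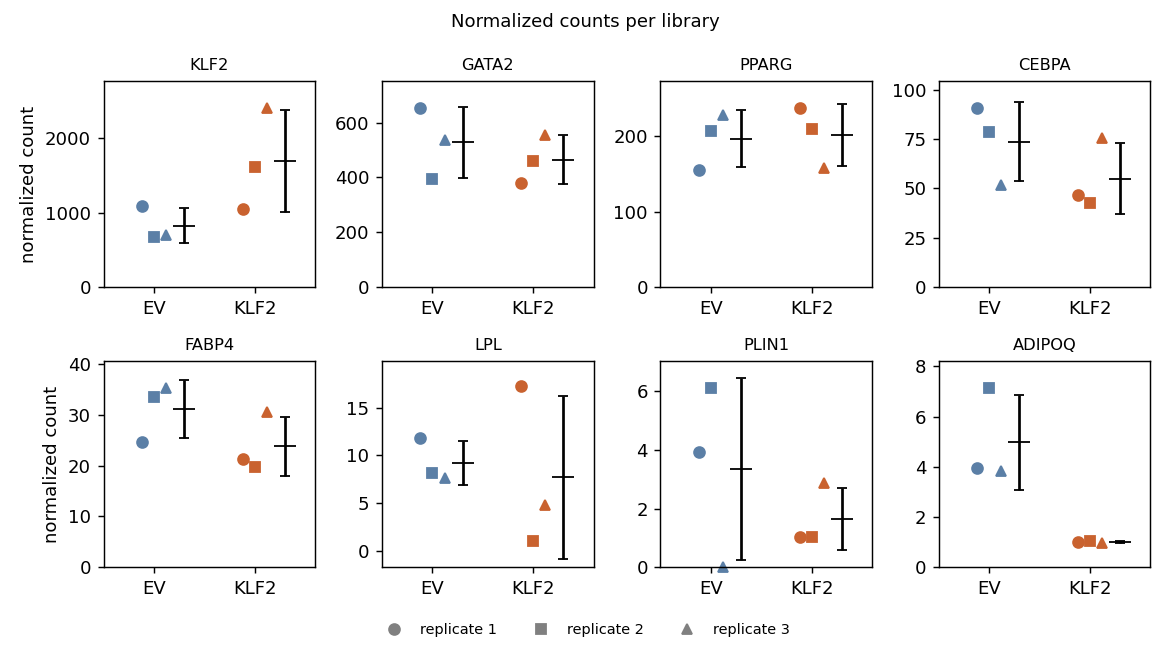
Normalized counts (y axis) of KLF2, GATA2 and the 6 adipogenic genes in EV and KLF2 libraries, 1 point per library; the horizontal mark and bar give the mean and SD of 3 libraries. KLF2 reached 2412 in KLF2 3, and its EV 1 value of 1093 lay above the 1052 of KLF2 1.

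In limma 0 of 16765 tested genes passed the threshold (lowest adjusted p = 0.962). On the recovered reads 0 of 11860 passed in edgeR and 0 of 18492 in DESeq2, each on its own set of genes. At an unadjusted p under 0.05 there were 354 of 16765 genes in limma (153 higher and 201 lower in KLF2 libraries), 154 of 11860 in edgeR and 173 of 18492 in DESeq2. Groups did not overlap for 5.62% of genes with a mean of at least 20, where chance gives 10% on average; the other 9 splits of the 6 libraries gave 2.52% to 28.5%. With EV 1 and KLF2 3 left out, 4 genes passed, among them KLF2 and RRM2, a subunit of ribonucleotide reductase. Leaving out KLF2 3 alone took the unadjusted count from 354 to 2081 and left 0 past the threshold.

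The values below did not pass the threshold and were chosen after they were seen. Among genes without overlap and with lower p, PERPB and PERPA, neighbouring genes related to the desmosome protein PERP, had higher means in KLF2 libraries: 121 ± 19.9 against 68.6 ± 10.4 and 24.7 ± 0.761 against 9.90 ± 2.02 (SD, n = 3). NEK10, SERPINB1 and TMC5 had log2 fold changes of 0.97, 0.84 and 1.32. SLC25A17, N6AMT1, IMMP1L, CENPP, NOP16, WDYHV1 and H2AFZ had log2 fold changes from 0.34 in H2AFZ to 0.61 in IMMP1L. Lower means were found for CLCF1, a cytokine of the interleukin 6 family, at 44.6 ± 21.3 against 95.8 ± 16.8 (SD, n = 3), and for PRELP, a matrix proteoglycan, at 41.5 ± 8.27 against 76.3 ± 9.95 (SD, n = 3). SPARC, COL5A1 and DUSP1 had log2 fold changes of -0.39, -0.39 and -0.42. MAP3K12, ST3GAL3, GNAO1, DAXX, LIX1L, TRPM2 and RUSC2 had log2 fold changes from -1.01 in MAP3K12 to -0.48 in LIX1L. Several of these overlap another gene by start and end on the chromosome, among them TMC5, CENPP, CLCF1, LIX1L and ST3GAL3. Whether their exons overlap was not examined, and reads from any shared stretch cannot be told apart.

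**Figure D2:**
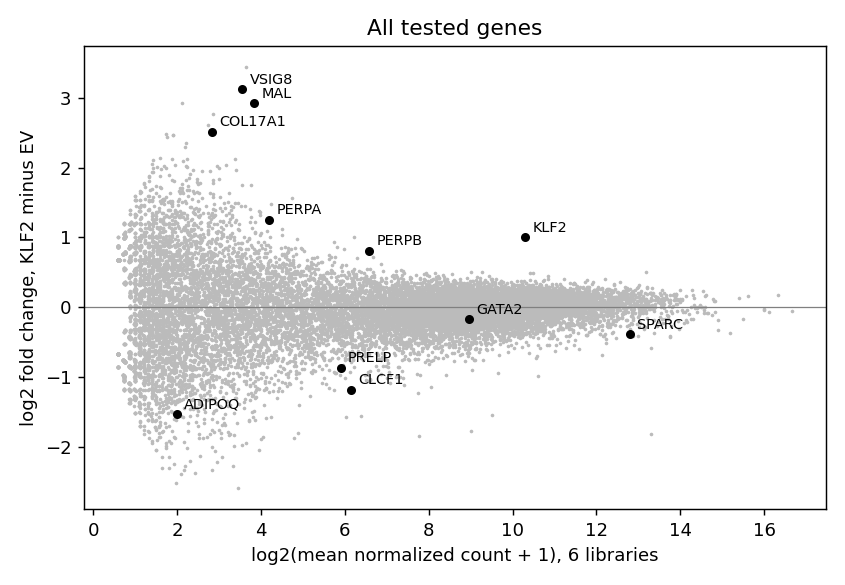
Log2 fold change, KLF2 minus EV (y axis), against log2 of the mean normalized count + 1 over 6 libraries (x axis) for the 16765 tested genes. KLF2, at a log2 fold change of 1.00, stood above other genes of its level, and GATA2 at -0.17 lay within them.

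By camera with the preset correlation, 6 of 31 lists passed, and 0 passed with an estimated correlation (lowest adjusted p = 0.569) or by directional fry (lowest adjusted p = 0.595). The number of lists past the threshold was 3 without EV 3, 4 without EV 1 and 4 without EV 2. In each list 0 members passed over all genes and 0 adjusted over the list alone. Interferon and cytosolic nucleic acid response genes fell as a set by the preset test, with 38 of 46 members lower. The median log2 fold change was -0.24 (camera adjusted p = 0.00033, and adjusted p = 0.608 with an estimated correlation of 0.149). The list's median deviation was 0.28, -0.11 and 0.16 in EV 1 to 3 and -0.15, -0.14 and 0.02 in KLF2 1 to 3, so EV 2 lay among the KLF2 libraries. The call ended without EV 3. IFIT5 had means of 6262 in KLF2 and 7917 in EV libraries, CMPK2 had 1118 and 1398, and ZNFX1 had 3284 and 4207. Mitochondrial encoded genes fell as a set by the preset test, with 13 of 13 members lower in mean and 0 of them at an unadjusted p under 0.05. The median was -0.29 (camera adjusted p = 0.00448, and adjusted p = 0.608 with an estimated correlation of 0.848). At that correlation the members moved together, so 13 of 13 are not independent observations. The list's median deviation was -0.33, 0.43 and 0.25 in EV 1 to 3 and -0.65, 0.24 and -0.04 in KLF2 1 to 3, so EV 1 lay below KLF2 2 and KLF2 3. The call ended without EV 2, EV 3 or KLF2 1, each left out alone, and with the length trend removed.

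Mitosis genes rose as a set by the preset test, with 36 of 50 members higher (median 0.11, camera adjusted p = 0.00842, and adjusted p = 0.608 with an estimated correlation). Its median deviation was -0.23 in EV 1, and KLF2 3 at -0.07 lay below EV 2 and EV 3. The call ended without EV 1 or KLF2 2, each left out alone, under quantile normalization, and with the microchromosome score (adjusted p = 0.196). MAD2L1, a spindle checkpoint protein, had means of 1440 and 1134, while FOXM1, a regulator of mitotic genes, was lower at 317 and 385. DNA replication genes rose as a set by the preset test, with 30 of 43 members higher in mean (median 0.08, camera adjusted p = 0.00842, and adjusted p = 0.569 with an estimated correlation). The call ended without EV 2, EV 3 or KLF2 2, each left out alone. PCNA, the sliding clamp of replication, had means of 9238 ± 1520 in KLF2 and 7350 ± 378 in EV libraries (SD, n = 3). Extracellular matrix genes fell as a set by the preset test, with 32 of 51 members lower in mean (median -0.17, camera adjusted p = 0.00842, and adjusted p = 0.569 with an estimated correlation). The call ended without EV 2 or KLF2 3, each left out alone. TIMP3, an inhibitor of matrix proteases, had means of 788 and 992. Immediate early genes fell as a set by the preset test, with 24 of 30 members lower in mean (median -0.15, camera adjusted p = 0.00842, and adjusted p = 0.608 with an estimated correlation). Their median deviation was 0.28 in EV 1 and -0.27 in KLF2 1, and KLF2 3 at 0.11 lay above EV 2 and EV 3. The call ended without EV 1 or KLF2 1, each left out alone, and with the microchromosome score (adjusted p = 0.286). EGR1 had means of 288 and 355.

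Lists on adipogenesis did not pass by camera in limma. Pro-adipogenic transcription factors had 14 of 19 members lower and a median log2 fold change of -0.22 (camera adjusted p = 0.0544), and passed under 4 of 26 alternatives: DESeq2, and, added after seeing the data, synonyms, the length trend removed and the residual component (adjusted p = 0.569 in limma with an estimated correlation). Medians were -0.04 for adipocyte and lipid droplet genes, -0.05 for anti-adipogenic regulators, -0.16 for GATA factors and cofactors, -0.06 for fatty acid synthesis, 0.03 for cholesterol synthesis and 0.04 for fatty acid oxidation. KLF2-responsive genes of endothelium and lymphocytes had a median of -0.08, and the KLF and SP family, which holds KLF2 itself, a median of -0.08. In this family KLF4 had means of 230 ± 102 in KLF2 and 318 ± 114 in EV libraries (SD, n = 3). NF-kB and inflammatory genes had a median of -0.11 (camera adjusted p = 0.0544); they passed under 11 of 26 alternatives, among them edgeR, DESeq2, voom and quantile normalization. Wnt signalling passed under 5 of 26, and cytosolic ribosomal proteins under 7. GATA factors and cofactors passed under 1, the residual component, and the unfolded protein response under 1, without EV 1 and KLF2 3. In limma with an estimated correlation the adjusted p was 0.608 for NF-kB and inflammatory genes, 0.608 for Wnt signalling and 0.831 for cytosolic ribosomal proteins. It was 0.608 for GATA factors and cofactors and 0.608 for the unfolded protein response. The other signalling and stress lists had medians of -0.02 for Wnt signalling, -0.08 for Notch signalling, -0.07 for TGF-beta and BMP signalling, -0.03 for insulin, IGF and PI3K signalling, -0.07 for the unfolded protein response, 0.03 for heat shock, -0.08 for cell cycle inhibitors and p53 targets, and 0.01 for cytosolic ribosomal proteins.

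Marker lists of cell types did not pass by camera either. Medians were -0.04 for preadipocyte and fibroblast markers, -0.02 for endothelial, 0.06 for leukocyte, 0.01 for muscle, -0.19 for bone and cartilage, -0.26 for epithelial and -0.04 for neural markers. The neural list had a fry mixed adjusted p = 0.00271, the only list past the threshold by that test, with members near the floor that went both ways, such as DCX with means of 0.318 in KLF2 and 2.62 in EV libraries and NEFL with 9.91 and 3.63. Median and mean differed in sign for heat shock, Wnt signalling, fatty acid oxidation, muscle, endothelial and neural lists.

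**Figure D3:**
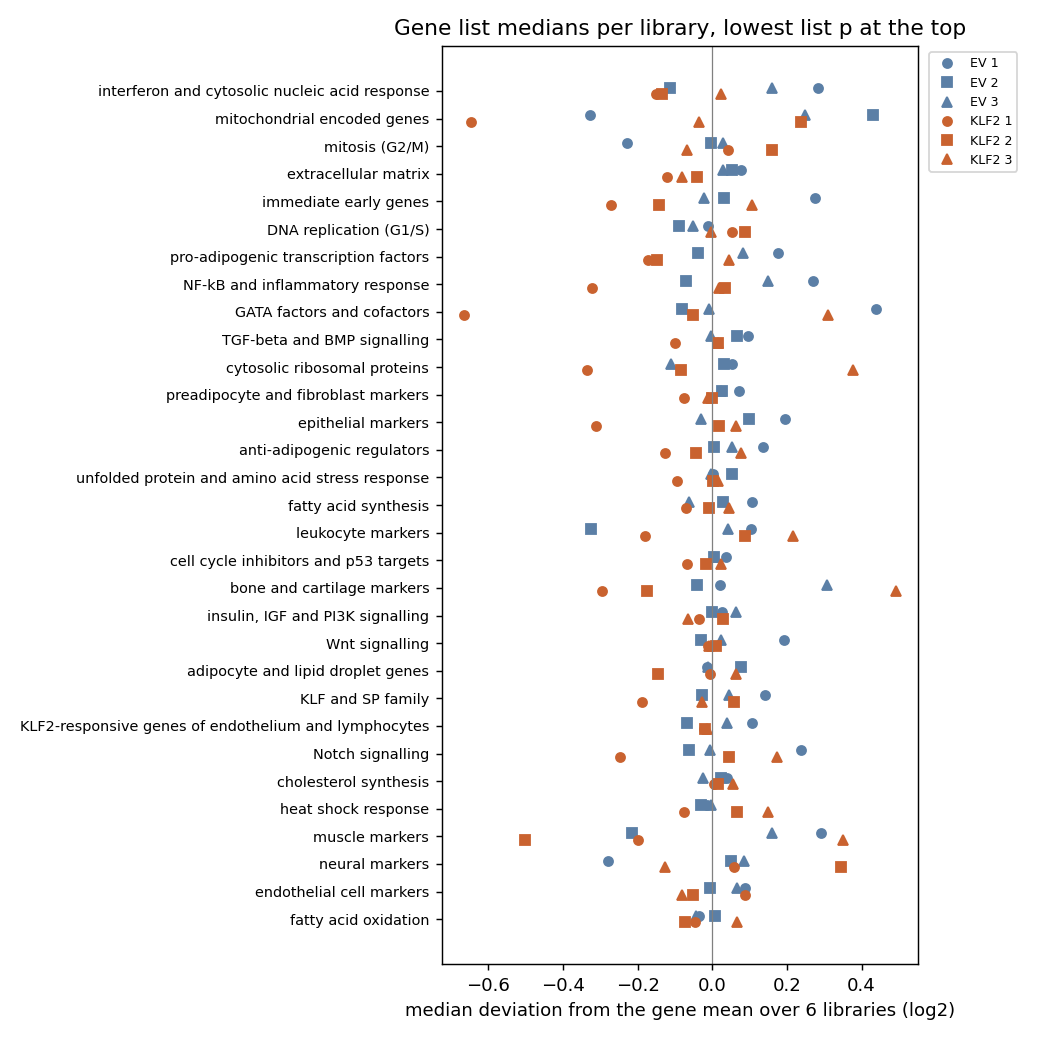
Median deviation from the gene mean over 6 libraries (x axis, log2) of each of 31 gene lists (rows, lowest list p at the top), 1 point per library. EV 1 and KLF2 1 lay farthest apart in several lists, for instance at 0.44 and -0.67 for GATA factors and cofactors.

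In the authors' deposited table, 0 genes passed an adjusted p of 0.05 and the lowest adjusted p was 0.661. DESeq2 on the recovered reads gave p-values within 9.0e-06 of the authors' deposited table for the 18492 genes with a p. The authors' deposited table listed a log2 fold change of 1.04 for KLF2 and -0.19 for GATA2. For KLF2 the authors' test gave an unadjusted p of 0.00030 and an adjusted p of 0.9999. Across 16765 genes, which are not independent replicates, the log2 fold changes here and in the authors' deposited table had a Pearson correlation of 0.881 and a Spearman correlation of 0.960.

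The libraries did not separate by group. The first principal component held 67.1% of the variance over 10893 genes with a mean of at least 20, with scores of 38.5, -5.52 and -2.00 in EV 1 to 3 and -42.5, -15.6 and 27.1 in KLF2 1 to 3. The Pearson correlation across genes, which are not independent replicates, was highest for EV 3 with KLF2 2 and with EV 2 (0.991 each) and lowest for EV 1 with KLF2 1 (0.939). As a check for a library deposited more than once, chi-square per gene was at least 6.25 for each pair, so none was a copy of another. MYL6, a myosin light chain, had 4110 normalized counts in EV 1, 2817 in KLF2 3 and 194 in KLF2 1. Genes of ribosomal RNA took 0.350% of assigned reads in EV 1 and 0.131% in KLF2 3, against 0.00162% to 0.0215% in the other libraries.

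**Figure D4:**
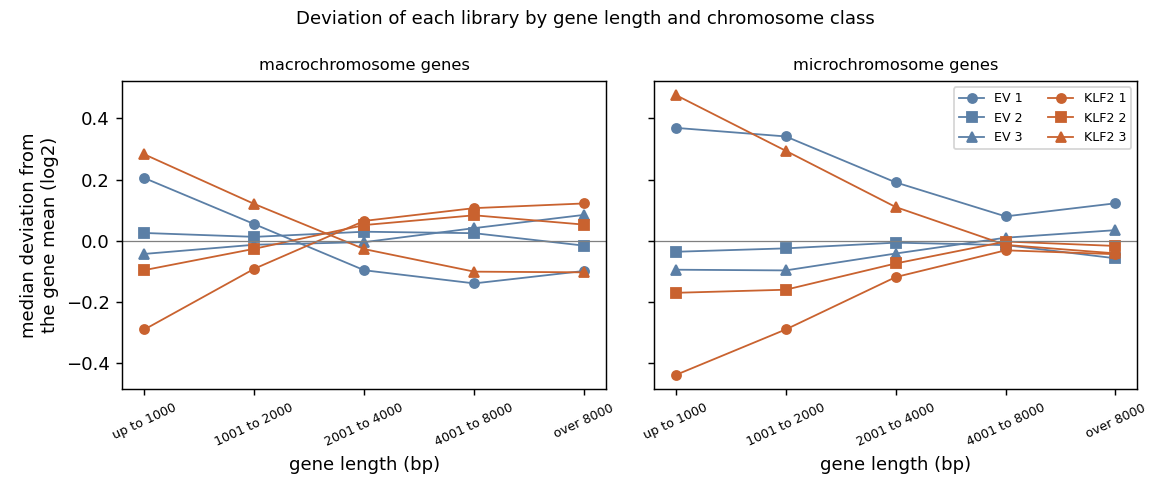
Median deviation of each library from the gene means (y axis, log2) by gene length (x axis, bp), for genes on macrochromosomes (left) and microchromosomes (right). Short microchromosome genes lay at 0.37 in EV 1 and 0.48 in KLF2 3 and at -0.44 in KLF2 1.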

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

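The alternatives without EV 1 and KLF2 3, with the length trend removed, with the score, with array weights, with the residual component and with synonyms were chosen after seeing the data. Running edgeR with TMM on the recovered reads was also decided then, though it was the design's test for raw counts. The count of 0 genes held under 22 of 26 alternatives, including every planned one. Among these, the stricter cuts on the same fit, an adjusted p below 0.01 and at least a 2-fold change, could not have raised it. It was 4 without EV 1 and KLF2 3, 2 with the microchromosome score (KLF2 and VSIG8), 10 with array weights and 246 with the first residual component. Other splits of the libraries gave up to 5450 genes with array weights and 3017 with the residual component, so those counts are not read as effects of KLF2. The cause of the differences was not tested.

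Leaving KLF2 out of the scaling gives no KLF2 value; it was higher under the other 23 alternatives, with a log2 fold change from 0.70 to 1.31 and an adjusted p from 2.83e-08 to 1.00. It passed under 4 settings, all chosen after seeing the data: 0.93 without EV 1 and KLF2 3, 1.31 with the score, 1.14 with array weights and 1.00 with the residual component. The residual component left the KLF2 fold change as it was and lowered p by construction, so passing with it is not support. Neither is passing without EV 1 and KLF2 3, since leaving out EV 1 ended the overlap of KLF2 by construction. GATA2 lay from -0.37 to 0.0074, passed in none of 24 alternatives, and turned to 0.0074 with the score.

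The count of 6 lists was 0 with an estimated correlation, 3 to 7 when each library was left out and up to 9 otherwise. It was 3 without EV 3. With the replicate number as a block, 0 genes and 6 lists passed. No pairing by number was seen: residual correlations of same-numbered libraries were -0.600, 0.144 and -0.511, and they did not all match best with their own number. These correlations cannot exclude a batch shared by number, since the first principal component held most of the variance between libraries.

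Of 1946 values for 85 named genes, 1902 kept sign and side, 29 passed the threshold and 15 turned sign, in 7 genes of small or noisy change. PPARG ranged from -0.13 to 0.20 when each library was left out, and was -0.16 with the score and -0.00875 with array weights. Leaving out each library alone gave LPL -1.55 to 0.031, PLIN1 -1.24 to 0.18, KRT5 -1.31 to 0.071 and CDH1 -1.26 to 0.045. Without EV 1 and KLF2 3 KRT5 was -1.58. At a pseudocount of 0.1 PLIN1 was 0.19 and CDH1 0.17. With the score CDH1 was 0.036, MYL6 0.074 and SERF2 0.031. Low counts limit what can be read from LPL, PLIN1, ADIPOQ, KRT5 and CDH1.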

Other observations

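All tests in this part were chosen only after the results they bear on were seen. Several genes near the floor in EV libraries were read in every KLF2 library, although none passed the threshold in limma without a correction for library differences. With array weights and with the residual component, both added after seeing the data, MAL, ENSGALG00010025927, DMGDH and VSIG8 passed. VSIG8 also passed with the microchromosome score, and COL17A1 with the residual component. Passing with the residual component is not support, since it lowers p by construction. MAL, a membrane protein of polarized epithelia and myelin, had 1.97, 2.04 and 2.87 normalized counts in EV 1 to 3 and 29.4, 24.9 and 18.2 in KLF2 1 to 3. The gene ENSGALG00010025927, described in the file as similar to a type II keratin, had means of 1.35 and 21.5. VSIG8 had means of 1.98 and 19.5, DMGDH had 0.976 and 11.4, and COL17A1, a hemidesmosome collagen, had 0, 1.02 and 2.87 in EV 1 to 3 and 17.3, 7.25 and 8.60 in KLF2 1 to 3. By start and end, VSIG8 overlaps CFAP45. ADAMTS15 was listed at 0 in the EV libraries and had a mean of 4.71 in KLF2 libraries. CCL21 was lower, with means of 5.36 in KLF2 and 18.8 in EV libraries, and so was LYG2, with 1.65 and 10.5.

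MAL, ENSGALG00010025927 and DMGDH were the 3 genes outside ribosomal RNA whose groups were at least 4 times apart, with a mean of at least 10. Epithelial cells in the KLF2 wells may be a source of such transcripts. Of 12 epithelial markers with an EV mean below 20, 0 had all KLF2 values above all EV values, a share of 0%; KRT5 and KRT14, abundant in stratified epithelium, had means of 2.60 and 2.62 in KLF2 and 3.59 and 4.21 in EV libraries. All 12 had means below 10 in both groups, too near the floor to exclude a small share of such cells, and the other 9 of the 21 measured markers were expressed in both groups. Of the 10 splits of the 6 libraries, 1, the real one, gave 3 such genes, and the highest of the others gave 1; 10 splits are too few for a share under 0.05. A response to KLF2 stays open too, as a hypothesis.

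Libraries differed mostly along an axis that did not follow the groups, with EV 1 and KLF2 3 on one side and KLF2 1 on the other. Gene length alone does not account for it, since the first component still held 64.2% of the variance after removal of the length trend, against 67.1% before. Ribosomal RNA taking up assigned depth does not either, since it took at most 0.350% of the reads assigned to genes. Reads not assigned to genes were not seen. The ribosomal RNA share still ranked the libraries in the same order as the first component, from 0.350% in EV 1 to 0.00162% in KLF2 1. What lies behind this shared order was not tested. Recovery that differs with chromosome class may contribute: microchromosome genes loaded above macrochromosome genes in 5 of 5 length bins. Base composition, which differs between chicken chromosome classes, is a candidate explanation that needs a genome sequence and was not tested; a difference in the state of the wells was not tested.

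KLF2 lies on a microchromosome, and its overlap between EV 1 and KLF2 1 may come from this axis. The microchromosome score explained 87.2% of its within-group variance, against a median of 63.3% over genes, so KLF2 is not unusual in this. With the score as a covariate the KLF2 log2 fold change was 1.31 (SE 0.12), where it was 1.00 (SE 0.31) without. An exchange of the labels of EV 1 and KLF2 1 stays open. With those labels exchanged KLF2 ranked 536 by p with the score, against 1 as given. Without the score it ranked 101, against 53, though its unadjusted p in limma was lower, at 0.0083 against 0.0126. The exchanged split gave 1207 genes at an unadjusted p under 0.05, against 354 as given. KLF2 values no longer overlapped, with a log2 fold change of 1.04, but that follows from EV 1 having lain above KLF2 1. The score was 1 of 4 corrections tried after seeing the data, and other splits gave up to 56 genes with it against 2 for the real one, so it does not make other calls safe.

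For the 2 counts in the report, all 10 splits gave 0 genes, as the real one did, with 0 as the highest of the others. Every split reaches a real count of 0 whatever the data hold, so the comparison of gene counts cannot decide. The real split gave 6 lists, the highest of the other splits gave 5, and 1 of 10 splits, the real one, gave 6. For the list count, the 10 splits are too few for a share under 0.05. The split of EV 1, EV 3 and KLF2 3 against the rest gave 3415 genes at an unadjusted p under 0.05, against 354 for the real one, which points to a structure of the libraries other than the groups.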
